A study of Mus musculus with 4 samples.

How the data were processed

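Liver RNA of fetal and maternal C57BL/6J mice was compared between food deprivation and control on 4 two-colour arrays of 1 slide. Per the labels, food-deprived RNA was in Cy5 and control RNA in Cy3 on the first array of each comparison, and the dyes were swapped on the second. Per the series' design text, 5 to 10 biological replicates were pooled per condition and the pooled RNA was dye-swapped. The labels number the pooled samples 1 and 2, but the number goes with the dye orientation, so the arrays of a comparison were treated as the same pools and counted as 1 replicate. No significance test was made for that reason, and no p-value is given.

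The deposited scanner files hold, per the file headers, intensity values of each spot on a linear scale: the mean pixel brightness of the spot and the median of its local background in both dyes. They also hold processed intensity values and the log10 ratio of red over green processed signal, which the scanner software had background-subtracted and dye-normalised, per the file headers. The headers name Agilent Feature Extraction 9.5.1.1, and the submitters' processing notes name 9.5.3.1. The deposited series table is a linear ratio of red over green processed signal rounded to 2 decimals. Its columns matched the scanner values of the same spots with a Pearson correlation of at least 0.9999 on the log scale. In the 2 columns with food deprivation in Cy5, 45017 of 45018 values are negative and none is positive (column medians -0.92 and -0.88), while all values of the other 2 are positive (medians 0.94 and 0.88). Its direction therefore follows from the match to red over green, the sign was dropped, and its meaning stays unknown.

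The main values came from R 4.3.3 with limma 3.58.1. Spot and local background intensities were corrected with normexp at an offset of 50, normalised within each array by loess with control spots at weight 0, and turned to food deprivation over control. Spots flagged as outliers were left out on their array (215 to 257 gene spots per array), spots of one probe were averaged, and control spots were removed. A probe counted as measured when the scanner software called the control channel, or the food-deprived channel, well above background on both arrays of the comparison. The probe with the highest mean intensity stood for a gene. Among called genes with over 1 measured probe, the probes did not all share a direction for 3 of 43 in the fetus and 7 of 200 in the mother. Of 41174 gene probes, 22944 were named through their accession in a RefSeq table of assembly GRCm38.p6, 5139 of them differently from the files, and 18230 kept the name in the files. No coordinates were used.

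The offset and the normexp step shrink the ratios of dim spots. On the second array of each comparison, 6 spots in the fetus and 4 in the mother had a stained local background, with net signals down to -3666 and -5973. Because normexp fits all spots, it added a median of 75.7 to 175.8 to dim spots on these arrays, against 49.2 to 58.2 on the others. The main values were kept as fixed, and an alternative with the local background of such spots (net signal under -20) set to the array median was added after seeing the data. It brought the amounts added back to between 48.8 and 57.9. A second addition was a stricter filter, with the signal over 10 SD above the negative controls. On all arrays at most 1.31% of the negative control spots were called well above background.

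A gene was called when its mean change was at least 2-fold and each array gave at least 1.5-fold in the same direction. The count that passes with the second array's sign unturned shows differences that follow the dye. Between the arrays of a comparison, red over green correlated at -0.63 in the fetus and -0.83 in the mother across probes, and the turned ratios at 0.67 and 0.86 across measured genes. The difference between mother and fetus used the same rule on arrays of equal dye orientation. Where a probe was not well above background in one condition on both arrays, the fold is a bound. It sets the mean of the bright channel against, per array, the higher of the dim signal and the lowest signal well above background, on log2 levels after loess and Aquantile normalisation. This applied to 1 called gene. The number of arrays limits the precision.

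Before the data were examined, 34 gene lists of pathways, cell type markers and sex chromosome genes were fixed. For each list with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on intensity in 20 bins. This describes these arrays and tests nothing about animals. The same placing was made on each array alone and with median centring after the data were seen. Of 33 such lists in the fetus 9 lay below and 10 above the range of 95% of random lists, and of 32 in the mother 10 lay below and 4 above, while randomly drawn genes give 5% outside. Members of a list can vary together, for which the 5% makes no allowance. Some genes stand in more than 1 list. The genes named in the text were the 8 largest rises and falls per comparison among genes with a symbol, the 4 members with the largest change per list, and the 5 largest differences between mother and fetus per direction. Further members past the rule are named where a list had few, and were chosen after their values were seen, which took the genes named past the about 30 per comparison planned.

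The rule and the list percentile were tested on simulated arrays made from the real differences between the arrays of a comparison. In the fetal simulation over 17996 genes, 60.0% of 50 genes changed 2-fold and all 50 changed 3-fold were called, and none of 17796 unchanged genes. In the maternal simulation over 16066 genes, 58.0% of 50 genes changed 2-fold and all 50 changed 3-fold were called, and none of 15866 unchanged genes. The changes were added to ratios already normalised, so the shrinking of dim spots by the offset and normexp is not covered. A change of 2-fold lies at the limit of the rule itself. These simulations cover technical error and not differences between animals. Tables, simulations and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

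The alternatives fixed in advance were no background correction, normexp with offset 0, the scanner software's log ratio, the series table, median centring in place of loess, Aquantile normalisation between arrays, no filter on dim probes, both channels above background, the mean over probes of a gene, other fold thresholds and leaving out each array in turn.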

Results

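Gene expression was measured in livers of C57BL/6J mice, a common inbred laboratory strain, on 4 two-colour Agilent arrays of 41174 gene probes. Each array carried RNA of food-deprived animals in one dye against RNA of control animals in the other, from fetuses on 2 arrays and from mothers on 2 arrays. The submitters pooled 5 to 10 biological replicates per condition and swapped the dyes, and the arrays of a comparison were treated as 1 pool per condition measured on both, although the labels do not settle whether the pools are the same. The differences below therefore have no replicate check, and the spread between the arrays of a comparison is read as technical. The length of the food deprivation, the stage of gestation and the sexes of the pooled fetuses are not given in the sources used here. A difference in sex between the fetal pools would be mixed with the response to food deprivation. The series title names the developmental origins of health and disease, and the comparisons ask which liver genes respond to food deprivation before birth and in the mother.

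Between 53.2% and 69.7% of gene spots were well above background per array and dye, and no spot was saturated. After loess normalisation the SD per array of the log2 ratio, from the difference between the arrays, of a gene was 0.15 in the fetus and 0.17 in the mother. A gene was called higher or lower when its mean change was at least 2-fold and each array showed at least 1.5-fold in that direction. "Rose" and "fell" are used below only for genes past this rule, and the values in brackets are log2 ratios of food-deprived over control liver on the first and the second array.

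In the fetal liver, the largest rise after maternal food deprivation was that of Pck1, which encodes the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis: it rose 12.3-fold (3.56 and 3.69). Cyp4a14, a fatty acid omega-hydroxylase, rose 4.49-fold (2.17 and 2.17), and Tat, the tyrosine aminotransferase, rose as well (2.23 and 1.77). The cold-inducible RNA-binding protein gene Cirbp rose 3.59-fold (1.97 and 1.71). Genes of lipid synthesis were among the largest falls, with Scd2 5.67-fold lower (-2.44 and -2.57), Scd1 5.32-fold lower (-2.33 and -2.50) and the fatty acid synthase gene Fasn 4.08-fold lower (-1.83 and -2.23). The transcript with the largest fall was Xist, the RNA that coats the inactive X chromosome of female cells. Its fall may come from the sexes of the pooled fetuses, a candidate explanation weighed further below. All 4 Xist probes were well above background in the control pool and not well above background in the food-deprived pool, which gives a fall of at least 6.89-fold for the brightest probe (-3.58 and -2.62), while the mean log2 ratios of the 4 probes of Xist ranged from -3.10 to -0.26.

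Among genes with a symbol, the other genes of the 8 largest rises were Cyp4a31 (1.83 and 1.89), Lhpp (1.82 and 1.89), the adrenergic receptor gene Adra2a (1.94 and 1.70) and the transporter gene Slco4c1 (1.90 and 1.69). The other large falls were those of the carbonic anhydrase gene Car3 (-2.11 and -2.04), Akr1c6 (-2.06 and -1.93), Dhcr7 (-1.95 and -1.77) and Serpina6, which encodes corticosteroid-binding globulin (-1.95 and -1.62). In all, 84 genes were called higher and 48 lower out of 17996 measured, which is 0.73% of them, and 8 of the called genes changed over 4-fold. No gene passed the same rule when the sign of the second array was left unturned, as a difference that follows the dye would. Of the called genes, 63.6% were higher, against 75.6% with median centring in place of loess. That setting called 68 genes higher and 22 lower, kept 86 of the 132 calls and left 488 differences that follow the dye. The scanner software's own log ratios called 231 higher and 172 lower.

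Of 24 measured genes of glycolysis and fatty acid synthesis, 10 fell and none rose, and none lay above 0 (median log2 ratio -0.81, against -0.09 to 0.10 for 95% of random lists of the same size and brightness). Besides Scd1 and Fasn, the falls included Pnpla3 (-1.95 and -1.50), the acetyl-CoA synthetase gene Acss2 (-1.57 and -1.65) and Srebf1, which encodes a transcription factor of lipid synthesis (-1.16 and -1.12). Of 25 genes of cholesterol synthesis and uptake, 8 fell and none rose (median -0.84). These included Dhcr7, Sc5d (-1.61 and -1.73), Fdps (-1.36 and -1.70) and Hmgcs1, the cytosolic HMG-CoA synthase (-1.36 and -1.46). With the mean over probes, at -0.96 for Acss2 and -0.99 for Hmgcs1, these calls are lost.

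Genes of fatty acid oxidation and targets of the fatty acid receptor PPARA lay on the other side. Of 35 measured, 7 rose and none fell (median 0.29, random lists -0.08 to 0.08), among them Cyp4a14, Cyp4a31, the lipid droplet gene Plin5 (1.45 and 1.86), Angptl4 (1.72 and 1.51) and Pdk4, an inhibitory kinase of pyruvate dehydrogenase (1.56 and 1.56). None of the 7 genes of ketone body synthesis passed the rule (median 0.29, percentile 98.9 of random lists), and on the first array alone the median was 0.09 (percentile 65.6). Gluconeogenesis had 4 rises among 17 genes and no fall (median 0.40): Pck1, the alanine aminotransferase gene Gpt (1.61 and 1.39), the glucose-6-phosphatase gene G6pc (1.35 and 1.33) and Got1 (1.26 and 1.21). Of 39 genes of amino acid catabolism and the urea cycle, 8 rose and none fell (median 0.60, random lists -0.08 to 0.08). They included Tat, Cth (1.62 and 1.62), Bhmt (1.35 and 1.75) and Aass (1.60 and 1.27).

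Glucocorticoid targets had 4 rises among 20 fetal genes (median 0.62): Tat, Gadd45b (1.64 and 1.55), Ddit4 (1.23 and 1.42) and the metallothionein gene Mt2 (1.74 and 0.89). Tat is also in the amino acid list and Ddit4 also in the list of ATF4 targets. In the clock list 1 of 17 genes rose, the transcription factor gene Tef (1.24 and 1.12), a call that is lost with the mean over its 3 probes (0.48), and the median was 0.30 (random lists -0.08 to 0.08). Related output genes of the clock lay near the 2-fold line, with mean log2 ratios of 0.91 for Dbp and 0.88 for Hlf. Of 53 drug-metabolising enzyme genes 6 rose and 2 fell (median 0.03). The largest of these were Cyp3a25 (1.69 and 1.77), the sulfotransferase gene Sult1d1 (1.35 and 1.32), Por, the electron donor of microsomal P450 enzymes (1.20 and 1.26), and Cyp2a4, which fell (-1.53 and -1.36). In the bile acid list the uptake transporter gene Slco1b2 rose (0.90 and 1.21), the only 1 of 18 genes past the rule (median 0.13, percentile 99.4, and 94.2 on the first array alone).

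Several fetal lists had a small shift in which few or no single genes passed the rule. The 46 cell cycle genes had a median of -0.24 (random lists -0.07 to 0.07), with 3 of them above 0 and none past the rule. With median centring in place of loess it was -0.032, where random lists lay between 0.131 and 0.285. The 39 erythroid markers had a median of -0.28 (random lists -0.08 to 0.09), which became 0.01 with median centring in place of loess, where random lists lay between 0.14 and 0.32. In the same comparison the endothelial markers had a median of 0.14 (percentile 99.7, 22 genes) and the bile duct markers -0.28 (random lists -0.11 to 0.11, 12 genes), none with a gene past the rule. Skeletal and cardiac muscle markers had a median of -0.12 (random lists -0.05 to 0.05, 22 genes), with the embryonic myosin gene Myh3 at -0.77. The heat shock and chaperone list stood at -0.32 (random lists -0.09 to 0.09), with 1 of 32 genes past the rule, Hsph1 (-0.98 and -1.31). With median centring the chaperone and bile duct medians were -0.11 and -0.13, both still below the range of random lists. Oxidative stress genes had a median of -0.16 and interferon response genes -0.12, and both medians turned positive with median centring, to 0.03 and 0.06, where random lists lay higher still (0.12 to 0.33 and 0.09 to 0.26). The chemokine gene Cxcl10 was the interferon gene past the rule (-1.13 and -1.63).

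Acute phase genes had a median of 0.09 (percentile 98.5), with Mt2 and Serpina3n (0.98 and 1.34) higher among 29. Lipoprotein and plasma carrier genes had a median of 0.19 over 23 genes (percentile 99.8), which turned from 0.40 on the first array to -0.07 on the second, with rises of Apoa5 (1.51 and 1.62) and Apob (1.17 and 0.89) and the fall of Serpina6. The call of Apob is lost with the mean over its 5 probes (0.60). The remaining fetal medians lay within the range of 95% of random lists, and their signs are not read as directions. They were 0.02 for ATF4 targets, where Trib3 (1.44 and 1.52) and Ddit4 rose among 26 genes, and 0.02 for the insulin and growth factor axis. They were -0.10 for genes typical of fetal hepatocytes, -0.07 for imprinted genes, -0.02 for DNA and histone methylation enzymes and 0.07 for autophagy and protein breakdown. Among cell type markers they were 0.11 for Kupffer cells (percentile 97.2), -0.02 for granulocytes and monocytes, -0.01 for lymphocytes, 0.07 for megakaryocytes and mast cells, -0.03 for stellate cells and fibroblasts and -0.03 for exocrine pancreas. Igfbp1 had a mean log2 ratio of 1.05 and missed the rule on the second array (1.59 and 0.51). The Y-linked genes Ddx3y and Eif2s3y had log2 ratios of 0.41 (0.57 and 0.24) and 0.38 (0.56 and 0.19), and the 5 genes of the sex chromosome list a median of 0.09. Only 3 placental markers were measured (median 0.05).

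In the maternal liver, the largest rise was that of Cidec, which encodes a lipid droplet protein, at 62.1-fold (6.03 and 5.88). Cyp4a14 rose 22.8-fold (4.76 and 4.26), the apolipoprotein gene Apoa4 14.6-fold (3.89 and 3.84), the acyl-CoA thioesterase gene Acot1 14.0-fold (3.85 and 3.78) and Pdk4 12.0-fold (3.63 and 3.53). The largest falls were those of Car3, at 14.4-fold (-3.84 and -3.85), and of the sterol synthesis genes Idi1, at 7.94-fold (-2.87 and -3.11), and Msmo1, at 7.31-fold (-3.15 and -2.59). Srebf1 fell 6.45-fold (-2.71 and -2.67).

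Among genes with a symbol, the other genes of the 8 largest maternal rises were the translation repressor gene Eif4ebp3 (3.67 and 3.60), the growth factor binding protein gene Igfbp1 (3.66 and 3.17) and the glycogen-targeting subunit gene Ppp1r3g (3.45 and 3.19). Among the 8 largest falls were also the water channel gene Aqp8 (-3.02 and -2.49), the retinoic acid hydroxylase gene Cyp26a1 (-3.00 and -2.51), Apol7a (-2.65 and -2.47) and Sqle, the squalene epoxidase gene (-2.50 and -2.59). In all, 249 genes were called higher and 303 lower out of 16066 measured, or 3.44%, and 87 of them changed over 4-fold. No gene passed the rule with the second array unturned. Of the called genes, 45.1% were higher, against 34.9% with median centring, which called 45 higher and 84 lower, kept 128 of the 552 calls and left 5929 differences that follow the dye. The scanner software's own log ratios called 656 higher and 810 lower.

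**Figure D1:**
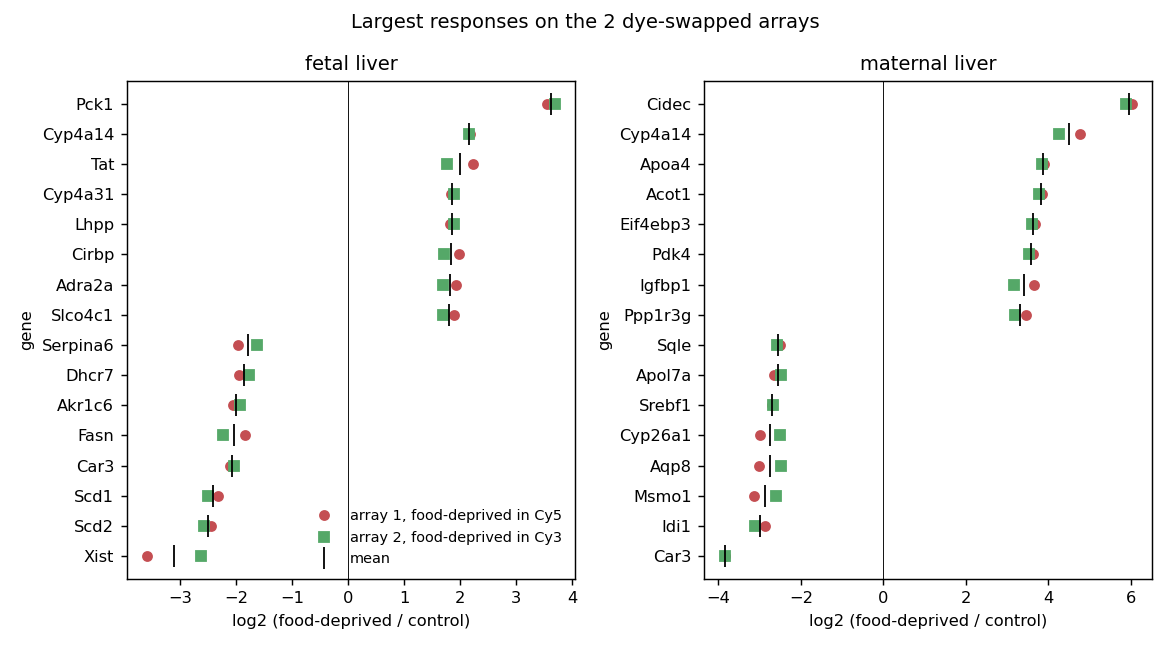
Log2 ratio of food-deprived over control liver (x axis) of the 8 genes with a symbol and the largest rise and the 8 with the largest fall past the rule in fetal liver (left) and maternal liver (right); circles and squares are the 2 dye-swapped arrays and the bar their mean. The arrays of Cidec lie at 6.03 and 5.88, and those of Xist lie farthest apart in the fetus, at -3.58 and -2.62.

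Fatty acid oxidation and PPARA targets had the highest maternal median: 20 of 34 measured genes rose and none fell, with a median log2 ratio of 1.18 (random lists -0.17 to 0.15). Besides Cidec, Cyp4a14, Acot1 and Pdk4 they included Cyp4a31 (3.16 and 3.12), Ehhadh (3.38 and 2.59) and Fgf21, which encodes a hormone of fasting (2.58 and 2.71). Ketone body synthesis genes had a median of 0.05 (percentile 60.2). The 1 of 7 past the rule was the transporter gene Slc16a6, which fell (-1.11 and -0.96), a call that is lost with the mean over its probes (-0.63). Of 18 gluconeogenesis genes 5 rose and none fell (median 0.27, percentile 99.4): Gpt2 (1.70 and 1.74), Got1 (1.84 and 1.56), G6pc (1.37 and 1.65), the glucose-6-phosphate transporter gene Slc37a4 (0.91 and 1.26) and Pck1 (1.13 and 1.00). Glucocorticoid targets had 6 rises among 18 genes (median 0.77, random lists -0.21 to 0.16), including Gadd45g (2.94 and 3.05), Lpin1 (2.01 and 1.99), Mt1 (1.83 and 1.40) and Sgk1 (1.75 and 1.46).

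Cholesterol synthesis and uptake had the lowest maternal median. Of 26 genes 19 fell (median -1.54, random lists -0.17 to 0.14), and the single rise was that of Insig2, whose product retains the sterol sensor in the endoplasmic reticulum (3.27 and 2.63). In glycolysis and fatty acid synthesis 7 of 24 genes fell and 2 rose (median -0.46, random lists -0.16 to 0.13). The falls included Srebf1, Thrsp (-2.35 and -2.46), Scd1 (-1.98 and -2.21) and Fasn (-1.68 and -1.88), while the fatty acid elongase gene Elovl5 (1.90 and 1.54) and the malic enzyme gene Me1 (1.23 and 0.97) rose. A further entry of Me1, counted apart under its older name Mod1, had a maternal mean of 0.53 and did not pass the rule. The bile acid list had 5 falls and 2 rises among 18 genes (median -0.23, percentile 1.76, and 18.6 on the second array alone). The export pump gene Abcb11 (-2.40 and -2.12), Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-2.12 and -2.06), and Slco1a1 (-2.20 and -1.54) fell, and the sterol 12-alpha-hydroxylase gene Cyp8b1 rose (1.19 and 1.55).

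Of 58 maternal drug-metabolising enzyme genes 12 fell and 1 rose (median -0.53, random lists -0.12 to 0.10). The falls included Aox3 (-2.62 and -1.96), the glutathione transferase gene Gsta3 (-1.90 and -2.46) and Cyp2f2 (-1.50 and -1.66), and the rise was that of Por (1.65 and 1.59). Oxidative stress genes had 3 falls and 1 rise among 27 (median -0.40, random lists -0.18 to 0.15), with Osgin1 at the largest fall (-2.51 and -2.24). Gsta1 and Gstm1, the other falls of that list, are also in the drug enzyme list, and its rise was that of Me1, whose Mod1 entry did not pass. In the amino acid list 5 genes rose and 1 fell among 34 (median -0.02, percentile 39.3). Aass (2.08 and 1.67), the tryptophan dioxygenase gene Tdo2 (1.61 and 1.62), the argininosuccinate lyase gene Asl (1.36 and 1.53), Sdsl (1.61 and 1.27) and Slc25a15 (1.18 and 0.98) rose, and the urea cycle gene Otc fell (-1.14 and -0.94), a call that is lost with the mean over its probes (-0.83). Tat had no maternal value, since its spot was flagged as an outlier on 1 array.

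Cell cycle genes had 10 falls and no rise among 40 in the mother (median -0.41, random lists -0.07 to 0.05), including Tk1 (-2.58 and -2.08), Cdc20 (-2.43 and -1.69), Birc5 (-2.19 and -1.72) and the cyclin D1 gene Ccnd1 (-1.53 and -1.39). Interferon response genes had 7 falls and no rise among 29 (median -0.57, random lists -0.12 to 0.09), including Cxcl9 (-1.57 and -1.13), Igtp (-1.37 and -1.28), Gbp3 (-1.28 and -1.07) and the immunoproteasome gene Psmb9 (-1.15 and -1.19). The Kupffer cell and macrophage markers, measured in the same pools, had a median of -0.49 (random lists -0.20 to 0.15). Of these 19 genes 4 fell, namely Adgre1 (-1.16 and -1.09), Aif1 (-1.07 and -1.01), Folr2 (-0.97 and -1.10) and Cd5l (-1.01 and -1.05), and the endotoxin co-receptor gene Cd14 rose (1.19 and 1.02). Among stellate cell and fibroblast markers 1 of 20 fell, the collagen gene Col3a1 (-1.42 and -1.72), and the median was -0.19 (percentile 0.99, and 11.7 on the first array alone).

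In the maternal chaperone list 5 genes fell and 1 rose among 32 (median -0.13, percentile 4.93). The falls were those of the endoplasmic reticulum genes Sdf2l1 (-2.05 and -1.93), Pdia6 (-1.45 and -1.57), Hyou1 (mean -1.27), Pdia4 (-1.27 and -1.19) and Pdia3 (-1.11 and -0.89), and the rise was that of the cytosolic Hspa8 (0.81 and 1.51). In the insulin and growth factor axis Igfbp1 and the leptin receptor gene Lepr (3.06 and 2.56) rose and Igfals fell (-1.58 and -0.95) among 26 genes with a median of -0.02. ATF4 targets had 3 rises among 20 genes (median 0.16, percentile 99.7, and 96.4 on the first array alone), namely Sesn2 (1.17 and 1.21, lost with the mean over its probes at 0.83), Cebpb (1.08 and 1.13) and Ddit4 (0.97 and 1.06), and the median turned to -0.002 with no filter on dim probes. Lipoprotein and plasma carrier genes had 3 rises and 3 falls among 24 (median 0.09, turning from 0.27 on the first array to -0.10 on the second), with Apoa4 and the fatty acid transporter gene Cd36 (1.95 and 1.74) higher and the transthyretin gene Ttr (-1.74 and -1.92) and Serpina6 (-1.37 and -1.58) lower. Acute phase genes had Mt1 higher and Saa4 (-1.51 and -1.59) and Hamp2 (-1.13 and -1.84) lower among 29 (median 0.04, turning from 0.13 on the first array to -0.11 on the second). In the autophagy list 3 of 26 genes rose (median 0.09, percentile 89.4, and percentiles 98.2 and 99.3 on the single arrays), the cathepsin gene Ctsl (1.56 and 1.52), Psmd4 (1.16 and 1.28, lost with the mean over its probes at 0.73) and Bnip3 (1.16 and 0.96).

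No maternal gene of the clock list passed the rule (median -0.07 over 17 genes). The same held for imprinted genes (median -0.09, percentile 2.36, and 9.07 and 27.0 on the single arrays), DNA and histone methylation enzymes (0.01) and genes typical of fetal hepatocytes (-0.09). It also held for the markers of erythroid cells (-0.07), granulocytes and monocytes (0.01), lymphocytes (-0.03), bile duct epithelium (-0.08), exocrine pancreas (0.05) and muscle (-0.05). Among endothelial markers Lyve1 rose (1.17 and 0.86, list median -0.16), a call that is lost with the mean over its probes (0.58), and among megakaryocyte and mast cell markers the von Willebrand factor gene Vwf rose (2.07 and 2.00, list median -0.01). Of the 2 measured placental markers neither passed (median -0.01), and Xist, the 1 measured gene of the sex chromosome list, had a log2 ratio of 0.03.

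**Figure D2:**
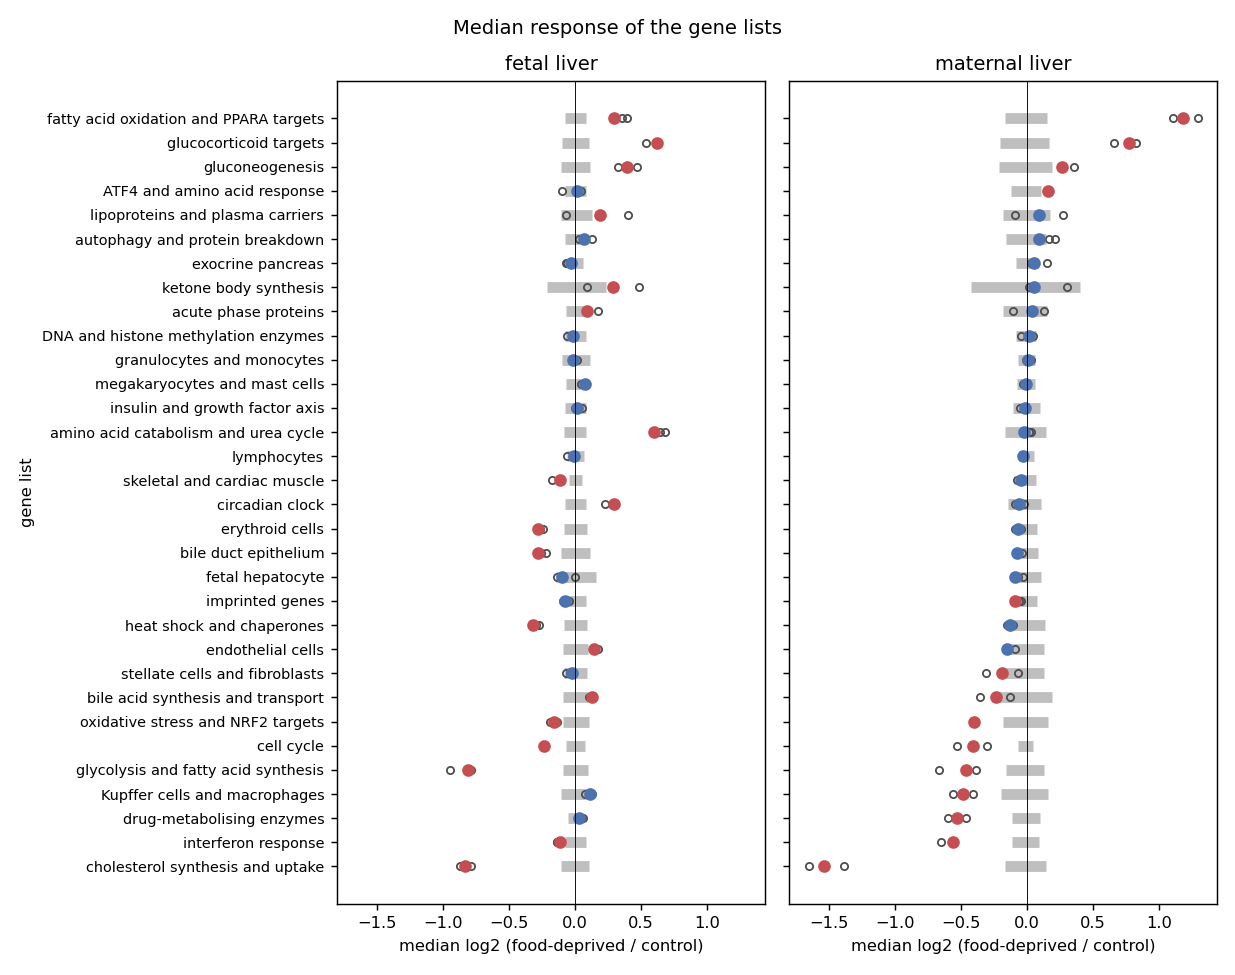
Median log2 ratio of food-deprived over control liver (x axis) for 32 gene lists (y axis) in fetal and maternal liver; filled points are medians of the gene means, red where outside the grey bar that spans 95% of random lists of the same size and brightness, and open circles are the medians on each array. Cholesterol synthesis and uptake lies lowest in both, at -0.84 and -1.54, and amino acid catabolism lies at 0.60 in the fetus and -0.02 in the mother. In the fetus glycolysis and fatty acid synthesis lies close by at -0.81, and lower on the first array (-0.95 against -0.87).

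Of the 15474 genes measured in both, 28 were called higher in both, where independent lists would share 1.05, and 22 were called lower in both, where independent lists would share 0.86. Calls shared in direction numbered 134 with the scanner software's own log ratios and 16 with median centring, in place of 50. The shared rises included Pck1, G6pc, Got1, Pdk4, Cyp4a14, Cyp4a31, Cyp4a10, Acot1, Angptl4, Apoa5, Aass, Por and Cirbp. The shared falls included Scd1, Fasn, Srebf1, Fdps, Dhcr7, Sc5d, Car3, Akr1c6, Aqp8 and Serpina6. Across genes, which are not independent replicates, the mean log2 ratios of fetus and mother had a Pearson correlation of 0.37 and a Spearman correlation of 0.29. Of 113 fetal calls measured in the mother 96 had the same sign there, and of 531 maternal calls measured in the fetus 415 had the same sign. Some of the genes named in this paragraph were picked after their values were seen.

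Only 3 genes were called in opposite directions, where independent lists would give 1.97. Upp2, a uridine phosphorylase gene, rose in the fetus (1.20 and 1.21) and fell in the mother (-2.13 and -1.59), as did the methyltransferase gene Inmt (1.25 and 0.96 against -1.99 and -1.77) and Lrtm1 (1.26 and 1.41 against -1.80 and -1.35). The response itself differed by the size rule, taken on the difference between arrays of the same dye orientation, for 460 genes. It was higher in the mother for 189 and lower for 271.

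Among genes with a symbol, the largest such differences were those of Cidec, whose response was 37.6-fold higher in the mother (fetal mean log2 ratio 0.72), Ppp1r3g (10.4-fold, fetal -0.06), Clstn3 (10.4-fold, maternal 2.54 and fetal -0.84) and Apoa4 (9.32-fold, fetal 0.65). Xist also passed, but its dim fetal signal gives only a bound, so its size and place are left open. In the other direction the largest differences were those of Upp2 (8.38-fold), Inmt (7.94-fold), Apol7a (7.66-fold, fetal 0.38), Lrtm1 (7.53-fold) and Cyp26a1 (6.92-fold, fetal 0.03). These differences have no test. The scanner software's own log ratios gave 1193 genes in place of 460, and the deposited ratios gave 1184 genes.

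**Figure D3:**
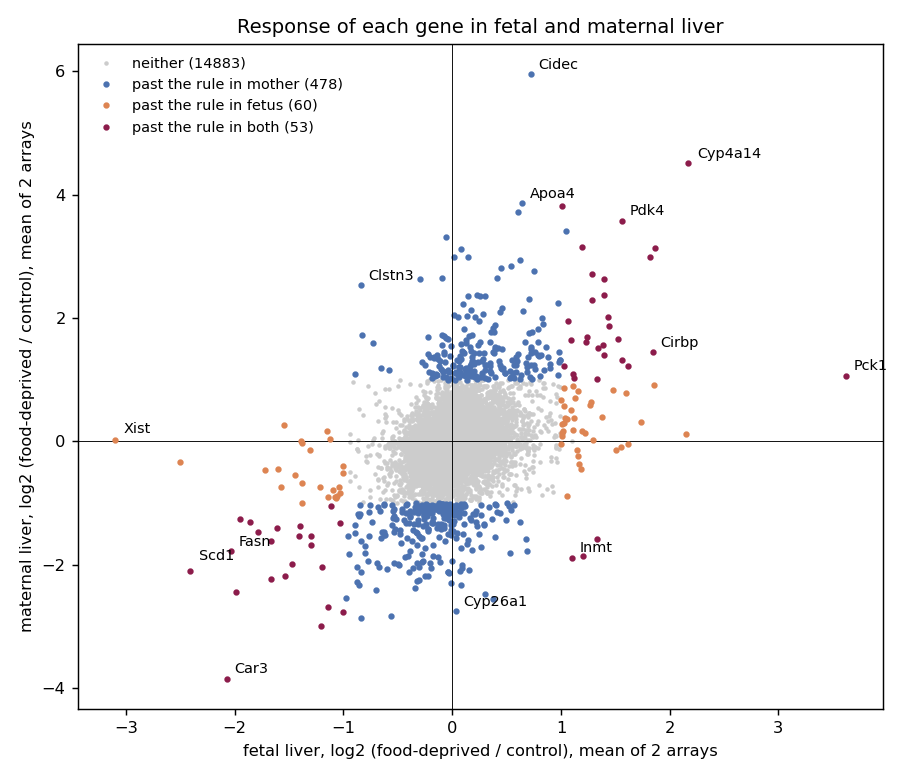
Mean log2 ratio of food-deprived over control liver in the fetus (x axis) and in the mother (y axis) for the 15474 genes measured in both, coloured by which comparison called them. Pck1 lies at 3.62 and 1.07, Cidec at 0.72 and 5.96, and Xist at -3.10 and 0.03.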

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

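The predictions on Y-linked genes were written after the fall of Xist was seen and before any Y-linked value was, the tests on erythroid markers were chosen only after the result was seen, and the demand that a value clear its spread was added to the tests of both patterns after their first values were seen, when the erythroid test was also widened from 5 to 9 lists. For the first results below, both arrays of the fetal comparison moved one way and both of the maternal comparison the other, and none of these differences was tested.

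Among named genes with at least 1.5-fold on each array, the differences of the log2 ratio, mother minus fetus, were -3.07 for Upp2, -2.99 for Inmt, -2.91 for Lrtm1, 3.38 for Clstn3 and 2.55 for Elovl5. They were 1.99 for Me1 (-0.89 in the fetus, 1.23 and 0.97 on the arrays of the mother), -1.94 for Slco1b2 (1.05 and -0.89) and -1.64 for the clock output gene Dbp (0.91 and -0.73). The Mod1 entry of Me1 had means of -0.85 in the fetus and 0.53 in the mother, where it did not pass the rule. Of the gene lists, bile acid synthesis and transport had a median of 0.13 in the fetus and -0.23 in the mother, a difference of -0.36, but the maternal median was -0.36 on the first array and -0.13 on the second, where it lay inside the range of random lists.

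Xist was at least 6.89-fold lower in the food-deprived fetal pool, with all 4 probes not well above background there, and did not differ in the mothers (log2 ratio 0.03). A candidate explanation is that the food-deprived fetal pool held few or no females and the control pool some. The median log2 ratio of the 4 measured Y-linked genes was 0.231, all of them above 0 on both arrays, as that explanation needs. Ddx3y (0.41) and Eif2s3y (0.38) carried it, while the dimmer Uty (0.09) and Kdm5d (0.03) lay near 0, and the X-linked genes Eif2s3x, Kdm5c, Kdm6a and Ddx3x, which escape X inactivation, lay at -0.34, -0.14, -0.04 and -0.03. By the bound written before the Y-linked values were seen, the median of 0.231 counts against a change of Xist alone. Under the demand added later, that each array clear the bound, such a change stays open. The Y-linked median was 0.35 on the first array but 0.12 on the second. The sexes of the pooled fetuses are not given in the sources used here. The second array is the one with stained backgrounds, where normexp added a median of 75.7 and 175.8 to dim spots, against 50.6 and 57.5 on the first. Whether this shrinking made the second value lower was not tested.

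The erythroid list of the fetus had a median of -0.28, with 10 brightest genes at -0.22. A trend with brightness is argued against: erythroid genes lay 0.28 below random lists of the same brightness with loess, and still stood apart with median centring, at -0.217 from their middle. A lower share of erythroid cells as the only change between the pools would raise the markers of all other cell types alike. Of 9 other lists the endothelial (0.14) and the bile duct list (-0.28) lay 0.425 apart (resampling range 0.10 to 0.62). That is past 0.37, the upper end of the spread that 1 common shift gives in resampling. For 5 of the lists, the 0.17 between the highest and lowest (resampling range 0.07 to 0.36) lay within their upper end of 0.23. The 9 lists argue, by a small margin, against a lower erythroid share as the only change, and the 5 do not. Because the bile duct list can differ for its own reasons, it cannot decide what lowered the erythroid list. A lower erythroid share as the cause of that fall, and a response of the erythroid genes themselves, stay open.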

How the results depend on the processing

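The replaced stained backgrounds and the stricter background filter were chosen after seeing the data. No paired analysis was possible because the replicate numbers mark the dye orientation and the results come from no test. The slide as a block was not run, since there is 1 slide.

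None of the 132 fetal and 552 maternal calls was called in the opposite direction under any alternative. Calls that fell under the rule were not checked for sign in this count. The scanner software's log ratios have no offset and come from its own background and dye steps. They gave 231 higher and 172 lower in the fetus and 656 and 810 in the mother, with 134 shared and 1193 differing. The series table gave 230, 171, 657, 811, 134 and 1184 in the same order. A threshold of 1.5-fold on each array gave 227, 116, 509, 679, 147 and 1175, as its looser rule must. Leaving out the offset alone, with normexp at offset 0, gave fewer calls than the scanner ratios. There were 115 higher and 73 lower in the fetus and 306 and 401 in the mother, and only the fetal falls moved past 1.5 times. Median centring gave 22 fetal falls, 45 maternal rises, 84 maternal falls and 16 shared calls, and kept 86 of the 132 and 128 of the 552 calls. The other counts stayed within 1.5 times. Replacing the stained backgrounds gave 93, 48, 289 and 344 calls, and the stricter filter 84, 48, 249 and 303.

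With 1 array left out, fetal rises ranged from 87 to 104, fetal falls from 47 to 53, maternal rises from 225 to 308, maternal falls from 267 to 369, shared calls from 50 to 58 and differing genes from 421 to 543.

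Among lists outside the range of random lists in the main setting, medians turned sign in 5 cases, and some medians inside that range also changed sign. With median centring the fetal oxidative stress list went to 0.026, interferon to 0.064 and erythroid cells to 0.014, all 3 still below the range of random lists, whose middle moved to between 0.17 and 0.23. The maternal ATF4 list went to -0.002 with no dim filter, and the fetal lipoprotein list to -0.066 without the first array (0.403 without the second). The cause of the last 2 was not tested. Of the other list values 728 moved by less than the SD between the arrays and 240 by more. The 728 include 65 values for each of the 2 other fold thresholds, which cannot move because a median does not use the threshold. Of the values of named genes 4148 kept their side of the rule, 104 fell under it and 119 passed it. Signal over background limits dim genes, whose ratios the offset shrinks.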

Other observations

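The tests on heat shock genes in this part were chosen after the result was seen.

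The control channels describe how fetal and maternal liver differ without food deprivation, as log2 levels set across arrays after Aquantile normalisation, which no array compared directly. Genes typical of fetal hepatocytes had a median difference, maternal minus fetal control, of -5.51 (8 genes), cell cycle genes -3.24 (40 genes), erythroid markers -2.97 (23 genes) and granulocyte and monocyte markers -3.37 (12 genes). Drug-metabolising enzymes had a median difference of 2.11 (51 genes), the bile acid list 1.51 (18 genes) and amino acid catabolism 1.51 (32 genes). Kupffer cell markers (-0.18) and endothelial markers (-0.01) lay close to each other in the 2 control pools. In the fetal control pool the level of Xist was 19.7% of that in the maternal control pool.

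Cirbp and Rbm3, whose transcripts are known to be induced by mild cold, had log2 ratios of 1.84 and 0.97 in the fetus and 1.45 and 2.25 in the mother. In the fetus the heat shock genes Hsph1, Hsp90aa1 and Hspa8 lay at -1.15, -0.70 and -0.58, while Hspb8 lay at 0.66. Of the 18 cytosolic and mitochondrial heat shock genes measured in the fetus, 6 lay above 0. A lower body temperature of the food-deprived animals could give higher Cirbp and Rbm3 in both, with lower cytosolic and mitochondrial heat shock genes. Their median was -0.20 in the fetus, but 0.226 in the mother (resampling range 0.03 to 0.43 over 18 genes), with Hspa8 at 1.16 and Hsp90aa1 at 0.61. For the mother this argues only against a form with lower heat shock genes. It cannot decide on a lower body temperature without lower heat shock genes, which stays open in the mother. A lower demand for protein folding that lowers both kinds of chaperone alike would leave their medians close. In the mother the endoplasmic reticulum chaperones had a median 0.997 below that of the heat shock genes (-0.997, resampling range -1.44 to -0.53), which argues against that form there. Whether a lower demand must lower both kinds alike was not tested. In the fetus both kinds lay below 0 (medians -0.41 and -0.20, difference -0.21), so a lower folding demand or body temperature stays open there, as does food deprivation acting by another route, which was not tested.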
